A study of Mus musculus with 6 samples.

How the data were processed

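Total RNA of cultured mouse tail tissue fibroblasts was profiled on 6 Agilent 1-colour arrays in 3 groups of 2, per the labels. Per the labels' protocols, RNA was isolated with TRIzol and a column kit, amplified with the Low Input Quick Amp kit and labelled with Cy3. The deposited scanner files give, per the file headers, intensity values from Agilent Feature Extraction 12.1.1.1, while the submitters' processing notes name version 9.5.1.1. Per the file headers, the processed signal is background-subtracted and detrended within the array, with dim spots at a surrogate value, and is not normalized between arrays. All 6 arrays lay on 1 slide and were scanned in 1 scan, so slide and scan could not be tested as batches. The control arrays lay in row 1 of the slide and the other arrays in row 2, so row and group cannot be told apart for the contrasts against control. Within row 2 the no.1 arrays lay in columns 1 and 2 and the no.2 arrays in columns 3 and 4. Column and group therefore cannot be told apart between no.1 and no.2. The series' value table, whose processing is not stated, held intensity values as deposited by the authors. On every array at least 99.9% of its values lay within 1% of the quantile-normalized processed signal on a linear scale, with a column median of 5.16, and its direction and scale are thereby known. No column of that table was without a sample (0 columns).

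The main values were log2 of the processed signal minus the array's 75th percentile over the 56605 non-control probes. Spots of 1 probe were averaged, and spots with an outlier flag were left out where the probe had others. Probe accessions, without versions, were matched to symbols in a RefSeq gene table of assembly GRCm38.p6, used for names only because the file headers name build mm9. A symbol was found for 32994 probes (58.3%), and 23611 kept the name in the file. Each gene was represented by its probe of highest mean, and 6361 tested genes had more than 1 probe. A gene was tested where that probe was well above background on both arrays of at least 1 group, which gave 23058 genes, 14080 with a symbol and 8978 unnamed. No probe was saturated. Levels of different probes were not set against each other.

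Tests used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the data.table package (1.17.8), with a mean per group over all 6 arrays and 3 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene is limma's. Changes are log2 fold changes with the moderated fit's SE. No design is stated in the labels beyond the groups, and the series' design text names the comparison of no.1 with no.2. A gene well above background on all arrays of 1 group and none of the other is given as a bound, the bright group's mean over the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own.

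Before the data were examined, 31 gene lists with 770 entries were fixed, as were the tests, the alternatives and the rule for genes named in the text. Of 752 distinct genes 18 stood in more than 1 list. The lists covered lysyl hydroxylases and crosslinking enzymes, collagens, other matrix proteins, filopodia, actin and focal adhesion, small GTPases, integrins, matrix proteases, TGF-beta response, YAP and SRF targets, hypoxia and glycolysis, unfolded protein response, cholesterol synthesis, lysosome, p53 targets, cell cycle, type I interferon response, cytokines, NRF2 targets, Wnt, growth factors, estrogen-responsive and xenobiotic genes, fibroblast identity, and 8 other cell types. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. The named genes are Plod1, Plod2 and Plod3, the 10 largest changes in each direction among called genes well above background on all arrays of both groups and changed alike in all 4 pairs of arrays, up to 4 called members of each list, and up to 3 bounds in each direction. Clone, locus and accession names were left out. 1 item that the rule takes is not reported here. Where fewer than 5 genes were called in a direction, the 10 of lowest p were taken, and where a list had no called member, the 2 of lowest p.

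The arrays were compared before averaging. On 277 probes with at least 8 spots, the SD of the difference between the control arrays was 0.046, and 26.7% of these probes differed by more than 2 standard errors of their spots, against 80.4% and 89.6% for the pairs of the other groups. Spot noise lies within an array, so this does not tell whether the control arrays carry 1 RNA or 2. They entered the fit as 2 samples because the labels list them so, and the main counts rest on that. A fit that averages them (2 residual degrees of freedom) was an alternative chosen after seeing the data.

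The fit was tested on simulated data with 200 of 23058 genes changed by known amounts. In the simulation of no.1 against no.2, 16.0% of genes changed by 1 on the log2 scale, 90.0% of those changed by 2 and all 50 of those changed by 4 were recovered, with 12 false calls. In that of no.1 against control these were 10.0%, 80.0% and 98.0%, with 10 false calls, and in that of no.2 against control 8.0%, 82.0% and all 50, with 19 false calls. Each simulated gene had the same spread in every group, while the real control arrays differed less than the other pairs. In the data 47.8% of genes were called in no.1 against control and 28.3% in no.2. The shares recovered in simulation therefore do not carry over to those contrasts. Camera called the 1 list shifted by 1 in each of the 3 simulations and none of the others. Genes were simulated independently of each other, so this does not test camera on lists of correlated genes. In the data the estimated correlation was 0.792 for the cell cycle list and 0.958 for the interferon list.

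Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median probe, no filter and a stricter filter on dim probes, the mean of a gene's probes, the replicate number as a block, only the groups of a contrast, a trended and robust prior, other thresholds, the value table, and leaving out each array in turn. The files used here have no column of mean spot signal, so normexp used the median spot signal in its place. Scaling to the 75th percentile of probes above background on all arrays, scaling to the mean log2 signal of the E1A spike-in probes, and averaging the control arrays were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.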

Results

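Gene expression was measured in cultured tail tissue fibroblasts of C57BL/6 mice with a conditional allele of lysyl hydroxylase 2 (LH2) and a CAG-Cre transgene. LH2 is encoded by Plod2 and hydroxylates lysines in the telopeptides of collagen, a step that sets which crosslinks collagen forms. The 6 samples fell into 3 groups of 2 arrays each. Control cells were kept in medium without tamoxifen. The no.1 cells had 24 h of tamoxifen and medium that contained it, and the no.2 cells had 24 h of tamoxifen and medium without it. Each RNA was labelled with Cy3 and hybridised to 1 Agilent mouse array. The file names carry 0 h for both control arrays and 24 h and 48 h within each of the other groups, while the labels give 24 h for all 4 arrays, so time in culture may also differ between the arrays of a group.

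Signal over background differed between the groups. Between 44.2% and 45.7% of 56605 probes were well above background on the control arrays, 53.4% and 53.5% on the no.1 arrays, and 48.4% and 48.6% on the no.2 arrays. The 75th percentile of the processed signal was 34.2 and 33.7 in control, 95.9 and 85.1 in no.1, and 55.1 and 56.9 in no.2, and every array was scaled to its own. The number of arrays limits the precision of every value. The control arrays nearly coincided, with r = 0.997 across probes and a robust SD of their difference of 0.14 on the log2 scale, against 0.38 between the no.1 arrays and 0.43 between the no.2 arrays. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Counts over all genes with both control arrays averaged into 1 sample therefore stand beside the main ones against control. Counts of list members are those of the main fit, and many of them were smaller with that averaging. The second no.1 array correlated more with the first no.2 array (r = 0.990) than with the first no.1 array (r = 0.983), while by the robust SD of the difference it lay nearer to the first no.1 array (0.378 against 0.397). The no.2 arrays differed more from each other (robust SD 0.433, r = 0.9842) than the second no.1 array did from either of them. Those robust SDs were 0.397 and 0.390, with r = 0.9899 and 0.9843. The first no.1 array lay further from the no.2 arrays (robust SD 0.623 and 0.645).

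**Figure D1:**
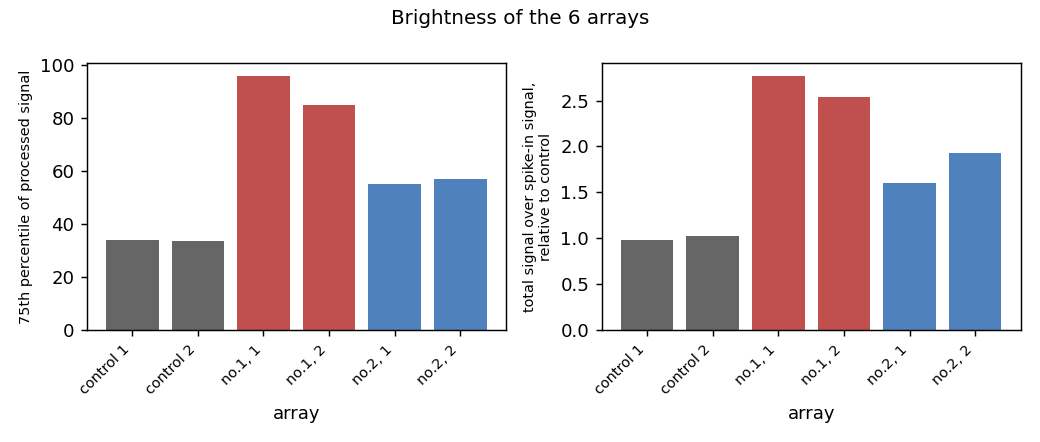
Brightness of the 6 arrays. Bars give, per array, the 75th percentile of the processed signal in arbitrary units (left, 33.7 to 95.9) and the total signal over the spike-in signal relative to the control mean (right, 1.60 to 2.77 on the 4 arrays of tamoxifen-treated cells).

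Plod2 signal fell in both groups of tamoxifen-treated cells. The single Plod2 probe read 42.1 and 34.9 on the control arrays, 31.8 and 17.1 on the no.1 arrays, and 13.3 and 8.59 on the no.2 arrays, and was well above background on all 6. After scaling, the mean log2 level was 0.18 ± 0.18 in control, -1.95 ± 0.51 in no.1 and -2.39 ± 0.48 in no.2 (SD, n = 2 each). Plod2 was 4.38-fold lower in no.1 than in control (log2 fold change -2.13, SE 0.34, adjusted p = 0.00613) and 5.92-fold lower in no.2 (log2 fold change -2.57, SE 0.34, adjusted p = 0.00767), in all 4 pairs of arrays each. Between no.1 and no.2 it differed by 0.43 (SE 0.34, adjusted p = 0.517), or by 0.076 without no.1 replicate 1, 0.095 without no.2 replicate 2, 0.79 without no.1 replicate 2 and 0.77 without no.2 replicate 1. With normexp background correction the Plod2 log2 fold changes were smaller, -0.95 in no.1 (adjusted p = 0.00184) and -0.83 in no.2 (adjusted p = 0.00824). The difference between no.1 and no.2 turned to -0.12 (adjusted p = 0.326). That correction adds an offset of 50, which lies above every Plod2 reading and shrinks the ratios of such signals. The size of the fall therefore depends on the background correction and its offset. Relative to the arrays' spike-in controls, the fall was -1.29 in no.2 (adjusted p = 0.0125) and -0.21 in no.1, which did not pass (adjusted p = 0.567), and no.1 and no.2 differed by 1.09 (adjusted p = 0.0711). Where this probe lies relative to the deleted part of the gene is not given in the sources used here, so its level is no check of the deletion itself.

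The other lysyl hydroxylases fell with it after scaling. Plod3 fell in no.1 (log2 fold change -1.59, SE 0.19, adjusted p = 0.00327) and in no.2 (-1.23, SE 0.19, adjusted p = 0.0103). Plod1 fell in no.1 (-1.35, SE 0.21, adjusted p = 0.00545), and its log2 fold change in no.2 was -0.69 (SE 0.21, adjusted p = 0.0525). The Plod3 call in no.2 was lost with the control arrays averaged (adjusted p = 0.0723). It was also lost without control replicate 1 (adjusted p = 0.0608) and without control replicate 2 (adjusted p = 0.0768). Relative to the spike-ins the log2 fold changes of Plod1 and Plod3 turned above 0, at 0.57 and 0.33 in no.1 and 0.58 and 0.037 in no.2, and none passed (smallest adjusted p = 0.0954). With normexp background correction they were -0.63 and -0.92 in no.1 and -0.30 and -0.82 in no.2, and the same 3 calls were kept.

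**Figure D2:**
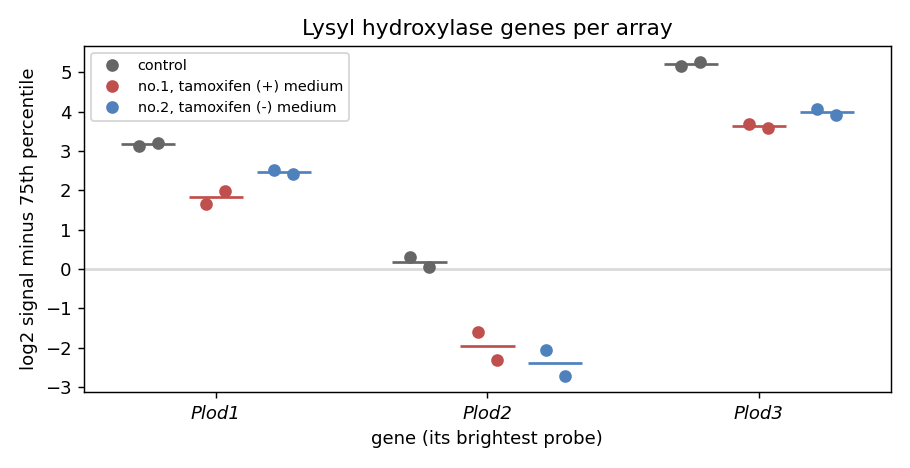
Lysyl hydroxylase genes per array. Points are log2 processed signal minus the 75th percentile of the array for the brightest probe of each gene, and lines are the means of 2 arrays. Plod2 sits near 0 in control and between -1.59 and -2.73 on the other 4 arrays, a fall that with spike-in scaling was -0.21 in no.1, while Plod1 and Plod3 turn above 0 with that scaling.

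The comparison the series is built on sets tamoxifen-containing medium (no.1) against tamoxifen-free medium (no.2) after the same 24 h of tamoxifen. No single gene passed the threshold, while by camera proliferation genes as a group were higher in no.1 and interferon-induced, lysosomal and collagen genes were lower. None of these list calls held with an estimated correlation (adjusted p = 0.604 with an estimated correlation for each). All 39 measured cell cycle and DNA replication genes were on the higher side in no.1, with a median log2 fold change of 0.65. Cenpf, a kinetochore protein, stood at 1.44 (SE 0.31) and did not pass the threshold (adjusted p = 0.282). All 27 type I interferon response genes were on the lower side, with a median of -1.51, which was -0.22 without no.1 replicate 1 (camera adjusted p = 0.0532).

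For single genes, limma called 0 of 23058 genes at an adjusted p under 0.05, where 3823 had an unadjusted p under 0.05 and the smallest adjusted p was 0.206. The pooled spread of this fit, and so each SE here, also takes in the nearly coinciding control arrays. Fitted to the arrays of no.1 and no.2 alone, limma again called 0 genes, and 2531 had an unadjusted p under 0.05. Among named genes well above background on all 4 arrays and on 1 side in all 4 pairs, those of lowest p on the higher side were Pde5a, a cyclic GMP phosphodiesterase (1.64, SE 0.24), the mitotic kinesins Kif20b (1.43, SE 0.22) and Kif18a (1.35, SE 0.24), Ccar1 (1.14, SE 0.19), Upf3b (1.13, SE 0.19), Ube2v2 (1.13, SE 0.21), the spindle gene Hmmr (2.15-fold), Filip1l (1.15, SE 0.22), Nexn (1.03, SE 0.19) and Smc6 (0.99, SE 0.19). On the lower side they were Tesc (-1.46, SE 0.21), Peli3 (-1.41, SE 0.29), Zfp575 (-1.34, SE 0.27), Actn3 (-1.28, SE 0.24), Lefty1 (-1.20, SE 0.24), Psd (-1.07, SE 0.22), Plin5 (-1.06, SE 0.19), Gprc5d (-0.95, SE 0.19), Rgs20 (-0.93, SE 0.19) and Impg1 (-0.92, SE 0.19). Each had an adjusted p of 0.282. Without the second no.1 array, limma called 2 genes higher and 115 lower.

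Of 31 gene lists, 11 were shifted against the other genes by camera, 3 up and 8 down, and none held with an estimated correlation (for each of the 11, adjusted p = 0.604 with an estimated correlation). Besides the cell cycle list (camera adjusted p = 1.07e-10), YAP and SRF target genes had a median of 0.45 (19 of 20 members higher, camera adjusted p = 0.0113) and estrogen-responsive and xenobiotic genes one of 0.71 (12 of 14 higher, camera adjusted p = 0.00385). Lower were the type I interferon response (camera adjusted p = 2.46e-06), lysosome genes (median -0.62, 24 of 26 lower), fibrillar and fibril-associated collagens (median -0.55, 14 of 17 lower), Wnt signalling targets and inhibitors (-0.47), matrix proteases and inhibitors (-0.46), matricellular and other matrix proteins (-0.44), fibroblast identity (-0.27) and lysyl hydroxylases and collagen crosslinking enzymes (-0.25). The last 2 had the highest camera adjusted p of the 11, 0.0280. Collagen examples were Col6a1 at -1.20 (SE 0.31) and Col5a3 at -2.32 (SE 0.65), and lysosomal ones the protease gene Ctsd at -0.87 (SE 0.23) and the hydrolase gene Hexa at -0.80 (SE 0.24), none of them called. With adjustment over the list alone, 4 cell cycle genes were called higher and 1 endothelial gene lower, against 0 over all genes. The protease gene Mmp9 also passed (-2.33, SE 0.30), but it was above background on 0 of 2 arrays in each group, so no change is read from it. The integrin list had a median of 0.013 and a mean of -0.12, the keratinocyte list a median of -0.088 and a mean of 0.0074, and the endothelial list a median of 0.15 with camera's direction down, none of them passing.

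The calls of all 8 lists on the lower side were lost with normexp background correction, as was that of the estrogen-responsive list, and the same 8 were lost without the filter on dim probes. Without it 8 lists passed, all up, among them actin and focal adhesion (camera adjusted p = 0.00440) and p53 targets (camera adjusted p = 0.00881), which did not pass with it. Camera then sets lists against dim probes at a surrogate value, and the median over all genes was -0.28. Losses and gains without the filter therefore say little about the lists themselves. The list shifts also rested on single arrays in several cases. Without the first no.1 array, the interferon median was -0.22 (camera adjusted p = 0.0532), the YAP and SRF median 0.11 (camera adjusted p = 0.475), the Wnt median -0.24 (camera adjusted p = 0.257) and the fibroblast identity median -0.22 (camera adjusted p = 0.0857). The crosslinking list lost its call in 13 of 19 alternatives, besides the estimated correlation, and fibroblast identity in 7. Among those 13, the crosslinking list missed the threshold with the control arrays averaged (camera adjusted p = 0.0682), without control replicate 1 or 2 (0.0682), no.1 replicate 2 (0.279) or no.2 replicate 2 (0.203). Without no.2 replicate 2, only 2 lists passed, cell cycle and interferon, and the medians were 0.19 for the estrogen-responsive list, -0.22 for matrix proteases, -0.26 for matricellular proteins and -0.40 for lysosome. The cell cycle median was 0.33 without no.1 replicate 1 and 1.01 without no.1 replicate 2, and the lysosome median -0.33 without no.1 replicate 1, with both calls kept. Without no.2 replicate 1 the protease median was -0.85 and the Wnt median -0.74. Without no.1 replicate 2 the medians were -2.98 for interferon, -0.72 for Wnt, -0.45 for fibroblast identity and -0.15 for the crosslinking list. With spike-in scaling the medians of the lists on the lower side, other than the interferon list at -0.85, were between 0.036 and 0.41.

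Against control, cell cycle and cholesterol synthesis genes were higher as lists in the no.1 cells by camera (for both, adjusted p = 0.568 with an estimated correlation). Ccna2, cyclin A2, rose by 4.16 on the log2 scale (SE 0.40), and Idi1, an enzyme of isoprenoid and cholesterol synthesis, by 4.78 (SE 0.38). Rarres2, the precursor of the chemoattractant chemerin (-8.70, SE 0.37), Serping1, the C1 inhibitor of complement (-8.33, SE 0.62), and the chemokine gene Ccl8 (-8.10, SE 0.61) fell. This comparison asks what tamoxifen treatment, with the deletion it is meant to bring about, changed in these cells. No group had tamoxifen with the gene intact, so tamoxifen, culture time and the deletion cannot be told apart against control.

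Limma called 11020 of 23058 genes (47.8%), 4940 higher and 6080 lower. With the control arrays averaged, it called 4845 (2260 higher and 2585 lower), of which 4801 were among the main calls. Without control replicate 1 the number was 5385, without control replicate 2 it was 4998, and without no.1 replicate 1 it was 5833. The split moved with the scaling, to 7564 higher and 3295 lower when arrays were scaled to the median probe and to 18916 higher and 426 lower relative to the spike-ins. The median over all tested genes was -0.12 with the 75th percentile and 1.81 relative to the spike-ins, so changes here are relative to the other genes of an array.

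The largest increases among genes measured on all arrays of both groups were those of Klra4 (6.37, SE 0.34) and Klra16 (5.86, SE 0.34). Both belong to the Ly49 receptor family, whose members are near-identical, so the probes may read other members. Ankrd1, a target of the YAP coactivator, rose by 5.17 (SE 0.34), Cd24a, a surface glycoprotein, by 4.65 (SE 0.56), Msln, mesothelin, by 4.27 (SE 0.41), Lmo7 by 4.07 (SE 0.27), Kif23, a kinesin of cytokinesis, by 4.06 (SE 0.32), and the forkhead factor Foxc2 by 3.94 (SE 0.65). The largest decreases besides those above were Gngt2 (-8.44, SE 0.49), the complement genes C2 (-7.97, SE 0.76) and Cfb (-6.83, SE 0.84), Ndufa4l2 (-7.90, SE 0.72), the matrix proteoglycan Prelp (-7.87, SE 0.83), the glutathione transferase Gsta4 (-6.92, SE 0.47) and the angiotensin receptor Agtr1a (-6.62, SE 0.96). All of these were in the same direction in all 4 pairs of arrays and kept their sign relative to the spike-ins. They passed with the control arrays averaged as well. At least 16-fold changes numbered 26 higher and 228 lower.

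Some genes were measured in 1 group only, and for these only a bound can be given. More probes were well above background on the no.1 arrays (53.4% and 53.5%) than on the control arrays (45.7% and 44.2%). The numbers of such genes in the 2 directions therefore cannot be set against each other. Of 1150 called genes well above background on both no.1 arrays and on neither control array, Unc5c, a netrin receptor, was at least 5.10-fold higher. Of 254 in the opposite state, Ctag2l2 was at least 29.8-fold lower, Cryzl2 at least 27.8-fold and Arsi at least 18.4-fold. These bounds hold for the main scaling only. The 75th percentile over spike-in signal was 3.86 and 3.73 times the control mean on the no.1 arrays. Relative to the spike-ins, bounds on falls would therefore be smaller and those on rises larger. The adjusted p was 0.000636 for Unc5c and 0.000198 for the others.

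Of the 31 lists, 10 were shifted against the other genes by camera, 2 up and 8 down, and none held with an estimated correlation. For lysosome and hypoxia it was adjusted p = 0.664 with an estimated correlation, for interferon adjusted p = 0.714 with an estimated correlation, and for the other 7 lists adjusted p = 0.568 with an estimated correlation. Of 39 cell cycle and DNA replication genes, 34 rose and none fell (median 2.16, camera adjusted p = 2.61e-13), among them Mki67 (3.61, SE 0.34), Top2a (3.14, SE 0.24) and the kinetochore motor gene Cenpe (3.14, SE 0.35). Of 24 cholesterol synthesis and uptake genes, 18 rose and 1 fell (median 1.70, camera adjusted p = 5.91e-06), with Msmo1 (3.14, SE 0.42), Hmgcs1 (3.08, SE 0.40) and Sqle (2.79, SE 0.33) after Idi1. Adjusted over the list alone the counts were 35 and 0, and 18 and 2. Both calls held in each of 19 alternatives other than the estimated correlation. These alternatives overlap, since the value table nearly repeats quantile normalization. Passes up with normexp or without the filter on dim probes add little, as the median over all genes was negative there.

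The 8 lists on the lower side passed at camera adjusted p between 0.000348 for lysosome and 0.0410 for growth factors, and their medians turned above 0 relative to the spike-ins, to between 0.12 and 1.24. All 8 calls were lost with normexp background correction, and all 8 were lost without the filter on dim probes. The median over all genes was -0.84 without the filter, as dim probes moved down with scaling. The loss of calls there therefore says little about these lists. Of 26 lysosome genes 16 fell and none rose (17 and 0 adjusted over the list alone), with the proteases Ctsk (-2.86, SE 0.31) and Ctsd (-2.20, SE 0.23). Of 23 lysyl hydroxylase and crosslinking genes 13 fell and none rose (13 and 0 adjusted over the list alone), with Lox, lysyl oxidase, at -2.50 (SE 0.29). Fewer of these crosslinking genes were called with the control arrays averaged. Of 32 cytokine and chemokine genes 15 fell and 2 rose (16 and 2 adjusted over the list alone). Of 25 oxidative stress and NRF2 target genes 12 fell and 1 rose (12 and 2 adjusted over the list alone), with Hmox1, heme oxygenase 1, at -3.29 (SE 0.24). Of 26 matrix proteases and inhibitors 14 fell and 3 rose (14 and 4 adjusted over the list alone), with the procollagen protease Adamts2 at -6.59 (SE 0.41). Of 34 growth factors and receptors 16 fell and 4 rose (18 and 4 adjusted over the list alone), with Igfbp6 at -4.69 (SE 0.39). Of 28 hypoxia and glycolysis genes 9 fell and 2 rose (9 and 2 adjusted over the list alone), with Aldoc, an aldolase, at -4.39 (SE 0.24) and the oxygen sensor Egln3 at 2.65 (SE 0.33). Of 27 type I interferon response genes 6 fell and none rose (0 and 0 adjusted over the list alone), and without no.1 replicate 1 the median moved from -1.81 to -0.49 (camera adjusted p = 0.205). The hypoxia call was lost without control replicate 2 (camera adjusted p = 0.0570) and without no.1 replicate 2 (0.0653), and the NRF2 call without no.1 replicate 2 (0.0742), where its median moved from -0.81 to -0.51. The lysosome median moved from -1.06 to -0.68 without no.1 replicate 1, with the call kept. Of 19 alternatives 8 lost the hypoxia call, 7 the NRF2 call and 6 each the protease, interferon and growth factor calls. The calls of the protease, interferon and NRF2 lists (0.0680) and of the growth factor list (0.0771) were lost without either no.2 array, which enters these contrasts only through the pooled spread. Relative to the spike-ins, Ctsk, Ctsd and Lox were below 0 but not called (adjusted p = 0.0882, 0.451 and 0.256).

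Lists on cell shape and adhesion did not pass with the filter on dim probes, and most had members called both ways. Without the filter, the filopodia, actin, small GTPase, TGF-beta and YAP and SRF lists passed (camera adjusted p at most 0.0244), all up by camera's direction, although the small GTPase median was -0.24. All of them but the small GTPase list also passed up with normexp background correction (at most 0.0337). The median over all genes was -0.84 without the filter and -0.23 with normexp. A list can pass up against such a background without having risen, so no rise is read from these passes. Of 28 filopodia genes 10 rose and 5 fell (10 and 5 adjusted over the list alone, median 0.51, camera adjusted p = 0.175). Fewer filopodia genes were called in each direction with the control arrays averaged. The formin Diaph3 rose by 2.33 (SE 0.37) and the Cdc42 effector Cdc42ep5 fell by 2.32 (SE 0.29). Myo10, the myosin of filopodia, rose by 1.61 (SE 0.30), a call lost without no.1 replicate 1 (1.33, adjusted p = 0.0513). Of 30 actin and focal adhesion genes 6 rose and 3 fell (5 and 3 adjusted over the list alone), led by the nonmuscle myosin Myh10 (2.58, SE 0.21), of 33 small GTPase genes 7 rose and 8 fell (7 and 8), led by Tiam2 (2.28, SE 0.19) and Pak3 (2.26, SE 0.19), and of 15 integrins 3 rose and 6 fell (3 and 7), led by Itgb3 (-3.40, SE 0.32). The median of the small GTPase list was -0.17, while its mean was 0.056 and camera's direction up. Relative to the spike-ins Cdc42ep5 was not called (-0.40, adjusted p = 0.353). Of 20 YAP and SRF targets 6 rose and none fell (2 and 0), and of 25 TGF-beta response genes 5 rose and 6 fell (5 and 5), with Tgfb2 at 2.83 (SE 0.29) and Ccn5 at -5.41 (SE 0.79).

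Matrix and fibroblast genes split as well. Of 23 matricellular and other matrix proteins 13 fell and 4 rose (13 and 4 adjusted over the list alone), with the small proteoglycan Dcn, decorin, at -3.73 (SE 0.44) and Tnxb at -3.89 (SE 0.31). Of 17 fibrillar and fibril-associated collagens 3 fell and 2 rose (3 and 2), and of 20 fibroblast identity genes 12 fell and 6 rose (12 and 6), with Thy1 at -2.22 (SE 0.19). With the control arrays averaged, the fibroblast identity genes still called were all on the lower side. The remaining response lists gave 7 lower and 3 higher of 26 unfolded protein response genes (7 and 3), 5 lower and 8 higher of 22 p53 targets (5 and 8), 8 lower and 2 higher of 21 Wnt genes (8 and 2), and 2 lower and 3 higher of 14 estrogen-responsive and xenobiotic genes (2 and 3), where the dioxin-inducible Cyp1b1 rose by 3.29 (SE 0.26). That list had a median of -0.18, a mean of 0.17 and camera's direction up. Relative to the spike-ins Thy1 was not called (-0.30, adjusted p = 0.314).

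No list of markers of other cell types passed camera (smallest camera adjusted p = 0.0752, for adipocyte and for macrophage and leukocyte genes). Few genes were tested per list and all medians were negative with the main scaling, so a shift of these lists is not excluded. The lower and higher counts were 4 and 0 of 9 macrophage and leukocyte genes (median -0.73), 3 and 2 of 12 keratinocyte genes (-0.46), 2 and 1 of 7 endothelial genes (-0.41), 5 and 0 of 8 pericyte and smooth muscle genes (-0.92), 6 and 1 of 11 skeletal muscle genes (-0.78), 3 and 2 of 11 cartilage, bone and tendon genes (-0.50), 5 and 1 of 8 adipocyte genes (-1.16), and 6 and 1 of 8 melanocyte and Schwann cell genes (-1.08). Csf1r, a macrophage receptor, fell by 2.40 (SE 0.41), a call lost relative to the spike-ins (-0.47, adjusted p = 0.189), and Eng, an endothelial and stromal coreceptor, fell by 3.30 (SE 0.19). Adjusted over the list alone the lower and higher counts were 4 and 0, 3 and 0, 2 and 2, 5 and 0, 6 and 1, 3 and 2, 6 and 1, and 6 and 1 in the same order.

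**Figure D3:**
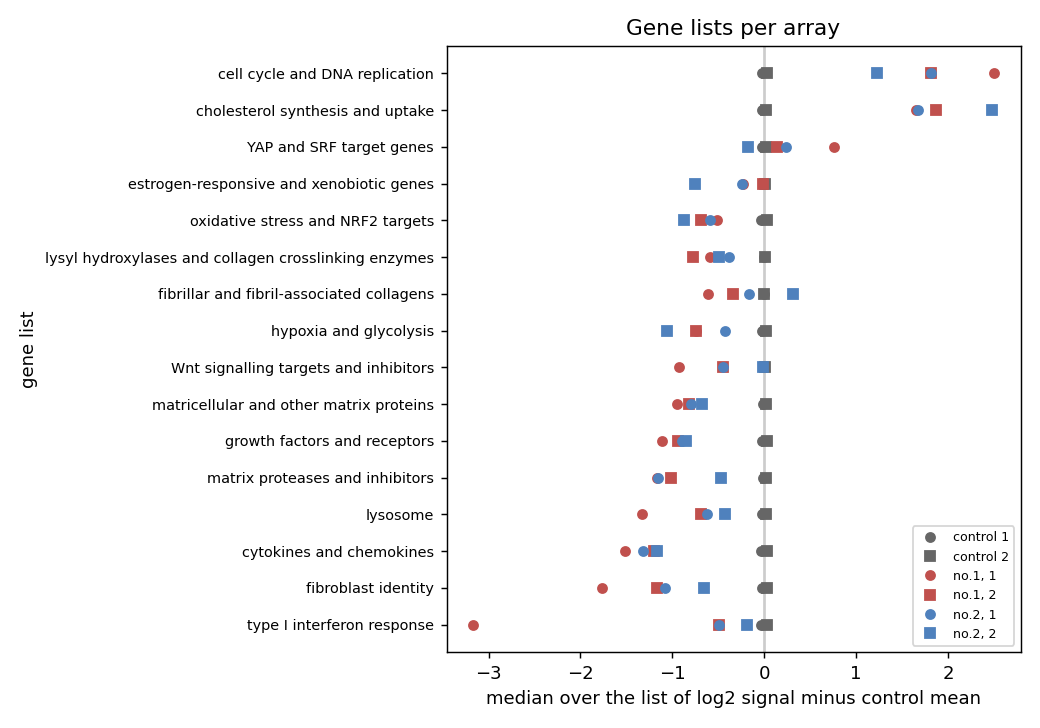
Gene lists per array. Each point is the median over a list of the log2 scaled signal minus the control mean, for the 16 lists that passed camera in at least 1 comparison. The first no.1 array stands at -3.17 for interferon-induced genes, where the other 3 arrays of treated cells lie between -0.50 and -0.18. With spike-in scaling the group medians against control lie above 0 for all 16 lists.

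Against control, cell cycle (adjusted p = 0.707 with an estimated correlation) and cholesterol synthesis genes (adjusted p = 0.636 with an estimated correlation) were higher as lists in the no.2 cells by camera. Idi1 rose by 4.30 (SE 0.38) and the mitotic checkpoint gene Bub1b by 2.46 (SE 0.23), while Rarres2 (-7.08, SE 0.37), Gngt2 (-7.23, SE 0.49) and Serping1 (-6.39, SE 0.62) fell. Among genes outside the leading ones of no.1, the homeobox gene Meox1 rose by 3.92 (SE 0.22) and the fibrillar collagen gene Col11a1 by 3.58 (SE 0.57). Parm1 (-6.30, SE 0.39), the small heat shock protein gene Hspb7 (-6.08, SE 0.58) and Crct1 (-6.05, SE 0.23) fell. These cells had the tamoxifen exposure of no.1 but not the tamoxifen-containing medium, and the same limit applies that no treated group kept the gene intact.

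Limma called 6517 of 23058 genes (28.3%), 2790 higher and 3727 lower, and 1246 with the control arrays averaged (577 higher and 669 lower), of which 1236 were among the main calls. Without control replicate 1 the number was 1710, without control replicate 2 it was 1298, and without no.2 replicate 2 it was 3010. The split was 3745 higher and 3106 lower with quantile normalization, 4841 and 2176 when scaled to the median probe, and 14898 and 544 relative to the spike-ins. The median over all tested genes moved from -0.10 to 1.17 with spike-in scaling. Other leading increases were Klra4 (5.42, SE 0.34), Msln (5.06, SE 0.41), Klra16 (4.87, SE 0.34) and Ankrd1 (4.36, SE 0.34). The calls of the cell cycle inhibitor gene Cdkn1c (4.72, SE 0.98) and of Nrep (3.43, SE 0.71) were lost with the control arrays averaged (adjusted p = 0.0704 and 0.0723), without either control array and without no.2 replicate 2. Other leading decreases were Ccl8 (-6.42, SE 0.61), C2 (-6.38, SE 0.76), Ndufa4l2 (-6.35, SE 0.72) and Gsta4 (-5.88, SE 0.47). As bounds with the main scaling, Unc5c was at least 4.03-fold higher and Ppef1 at least 35.3-fold lower. The 75th percentile over spike-in signal was 1.98 and 2.95 times the control mean on the no.2 arrays. Relative to the spike-ins the bound on Ppef1 would therefore be smaller.

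Of the 31 lists 7 were shifted by camera, 2 up and 5 down, and none held with an estimated correlation. For cell cycle and hypoxia it was adjusted p = 0.707 with an estimated correlation, for lysosome adjusted p = 0.818 with an estimated correlation, and for the other 4 lists adjusted p = 0.636 with an estimated correlation. Of 24 cholesterol genes 19 rose and none fell (20 and 1 adjusted over the list alone, median 2.12, camera adjusted p = 1.55e-10), with Hmgcs1 at 3.26 (SE 0.40) and Cyp51 at 2.81 (SE 0.34). Of 39 cell cycle genes 28 rose and none fell (33 and 0 adjusted over the list alone, median 1.55, camera adjusted p = 1.57e-11), with the proliferation factor Foxm1 at 2.42 (SE 0.29). Far fewer single cell cycle genes were called with the control arrays averaged, while the list kept its camera call. On the lower side were hypoxia and glycolysis (median -0.77, camera adjusted p = 0.00838, 8 of 28 fell and 2 rose, 10 and 2 adjusted over the list alone), oxidative stress and NRF2 targets (-0.61, camera adjusted p = 0.00838, 12 of 25 fell, 12 adjusted over the list alone), cytokines and chemokines (-1.16, camera adjusted p = 0.0176, 11 of 32 fell and 2 rose, 14 and 3 adjusted over the list alone), growth factors and receptors (-0.97, camera adjusted p = 0.0354, 11 of 34 fell and 2 rose, 14 and 2 adjusted over the list alone) and lysosome genes (-0.51, camera adjusted p = 0.0281, 5 of 26 fell, 5 adjusted over the list alone). All 5 calls were lost with normexp background correction, and all 5 were lost without the filter on dim probes. The median over all genes was -0.56 without the filter, so the loss of calls there says little about these lists. Without no.2 replicate 2 the hypoxia median moved from -0.77 to -0.42, with the call kept. The medians of these 5 lists were 0.11 to 0.76 relative to the spike-ins, and without no.2 replicate 1 only the hypoxia list of the 5 passed. The lysosome call was also lost without control replicate 2 (camera adjusted p = 0.0765), and in 8 of 19 alternatives in all. Aldoc (-3.91, SE 0.24), Gdf15, a stress-induced cytokine (-4.59, SE 0.39), and Hmox1 (-3.15, SE 0.24) fell.

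Of 28 filopodia genes 6 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.293). All of these single-gene calls were lost with the control arrays averaged. The filopodia list passed with camera's direction up without the filter on dim probes (camera adjusted p = 0.00785) and with normexp background correction (0.0457). The median over all genes was -0.56 without the filter and -0.12 with normexp, so no rise of the list is read from these passes. Myo10 rose by 1.54 (SE 0.30) and the actin bundling gene Fscn1 by 1.18 (SE 0.32), calls that were lost with the control arrays averaged (adjusted p = 0.0794 and 0.149), without either control array and without no.2 replicate 2. The Fscn1 call was also lost without no.2 replicate 1 (adjusted p = 0.0668). Myh10 rose by 2.31 (SE 0.21) and Tiam2 by 2.21 (SE 0.19), and Itgb3 fell by 2.71 (SE 0.32). Lox fell by 2.35 (SE 0.29), a call lost relative to the spike-ins (-1.07, adjusted p = 0.0670), with 5 of 23 crosslinking genes lower (4 adjusted over the list alone). No type I interferon response gene was called among 27 (median -0.29). Median and mean, or camera's direction, differed in sign for p53 targets (-0.12 and 0.0047), YAP and SRF targets (-0.034 and 0.13), small GTPases (-0.30 and -0.011, camera up), the TGF-beta response (-0.013 and -0.12, camera up) and cartilage, bone and tendon genes (0.48 and -0.094, camera up), none of them passing.

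Both contrasts against control called 2516 genes higher and 3293 lower in common, 5809 in the same direction, and 4 in opposite directions. Independent lists of these sizes would share 597.7 higher and 982.7 lower. At an unadjusted p under 0.05, 8893 genes passed in the same direction in both contrasts, against a mean of 378 in 20 simulated sets of unchanged groups with shared controls. With the control arrays averaged, the number in the same direction was 1161. Without control replicate 1 it was 1568, without control replicate 2 it was 1198, and without no.2 replicate 2 it was 2899. The contrasts share their 2 control arrays, too few to give each contrast its own pair, so part of the excess may come from them.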

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

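The tests of explanations for the interferon genes and the spike-in comparison were chosen after the results were seen. The effects of tamoxifen treatment differed between no.1 and no.2 for 11 gene lists by camera's test of the difference. None held with an estimated correlation (for each, adjusted p = 0.604 with an estimated correlation). The median differences (no.1 minus no.2) were 0.651 for cell cycle and DNA replication, 0.449 for YAP and SRF targets, 0.71 for estrogen-responsive and xenobiotic genes, -1.51 for the type I interferon response, -0.617 for lysosome, -0.547 for collagens, -0.465 for Wnt genes, -0.456 for matrix proteases, -0.435 for matricellular proteins, -0.267 for fibroblast identity and -0.248 for crosslinking enzymes. Without no.2 replicate 2 only 2 lists passed, and the medians were 0.19 for the estrogen-responsive list, -0.22 for matrix proteases, -0.26 for matricellular proteins and -0.40 for lysosome. Without no.1 replicate 1 only 7 passed, and the medians were 0.33 for cell cycle, 0.11 for YAP and SRF, -0.22 for interferon, -0.33 for lysosome and -0.24 for Wnt genes. Without no.1 replicate 2 they were 1.01 for cell cycle, -2.98 for interferon, -0.72 for Wnt genes, -0.45 for fibroblast identity and -0.15 for crosslinking enzymes, and without no.2 replicate 1 -0.85 for proteases and -0.74 for Wnt genes. The crosslinking call was lost in 13 of 19 alternatives besides the estimated correlation, and the fibroblast identity call in 7. The 8 calls on the lower side were lost with normexp background correction and without the filter on dim probes. Lists are set against dim probes at a surrogate value when the filter is left out, so that loss says little about them.

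Both no.1 arrays and both no.2 arrays lay on opposite sides of control for 11 named genes with the main scaling. The differences (no.1 minus no.2) were 1.64 for Pde5a, 1.14 for Ccar1, 1.16 for Inhba, 0.805 for Pmaip1, 1.60 for Ptgs2, 0.636 for Krt10, -1.06 for Plin5, -1.20 for Col6a1, -2.00 for Itga11, -0.51 for Mvk and -1.31 for Gstm1. Each was tested in the contrast of no.1 with no.2 and missed the threshold (adjusted p = 0.282).

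The spike-in probes, which no comparison uses in its main form, showed more sample signal per spike-in signal in the treated cells. Relative to the control mean, total signal over spike-in signal was 2.77 and 2.54 on the no.1 arrays and 1.60 and 1.93 on the no.2 arrays.

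The low interferon-induced genes of no.1 came from 1 array. The median over 27 genes was -3.17 below control on the first no.1 array and -0.49 on the second, a median difference of -2.64 between them, while all genes differed by 0.02. Scaling or dim signal on that array is argued against, since 0.01% of random lists matched on mean signal were as low, the smallest share they can give. On that array 96.3% of the genes (26 of 27) were more than 2-fold lower than on the other array of the group, but the file names give these arrays 24 h and 48 h. Tamoxifen in the medium, acting with time, and a state of that 1 culture cannot be told apart, since only 1 array showed a median more than 2-fold below control.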

How the results depend on the processing

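Averaging the control arrays, scaling to the spike-ins and scaling to probes above background on all arrays were chosen after seeing the data. Signal over background limits what can be tested, since 44.2% to 53.5% of probes were well above background. Where an array was left out, the lone array of its group was assumed to vary like the other groups. Of 131 named genes called in no.2 against control, 71 kept the call without control replicate 1 and 66 without control replicate 2, and of 143 in no.1 against control 118 and 114 did. Quantile normalization kept 136 and 118 named calls in no.1 and no.2, and scaling to the median probe 137 and 118. The list calls for cell cycle in all 3 contrasts and for cholesterol in both contrasts against control were kept in 19 alternatives other than the estimated correlation. The value table nearly repeats quantile normalization among these. Passes up with normexp or without the filter on dim probes add little, as the median over all genes was negative there.

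Leaving out 1 array at a time gave 0 to 117 genes and 2 to 15 lists in no.1 against no.2, with Plod2 at 0.076 to 0.79. In no.1 against control it gave 4998 to 12052 genes and 6 to 10 lists, with Plod2 at -2.49 to -1.77. In no.2 against control it gave 1298 to 6361 genes and 3 to 8 lists, with Plod2 at -2.90 to -2.23. The genes shared by both contrasts numbered 1198 to 5555.

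With the replicate number as a block, limma called 0, 10572 and 6055 genes and camera 13, 11 and 7 lists in the 3 contrasts, with 5356 genes shared. Across genes, deviations from the group means correlated at -0.035 and -0.017 between control and the treated groups, and at 0.165 between no.1 and no.2. In both treated groups the file names give 24 h to replicate 1 and 48 h to replicate 2, so the block may also carry time there. The adjusted p of Plod2 with the block was 0.00303 in no.1 and 0.00345 in no.2.

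At an adjusted p under 0.10, 9789 genes were called in no.2 against control. With the control arrays averaged the counts were 4845 in no.1, 1246 in no.2 and 1161 shared, with 1 degree of freedom fewer. With an estimated correlation 0, 0 and 0 lists passed in the 3 contrasts. Without a filter on dim probes the counts were 8296 in no.1 against no.2, 24872 in no.1, 16476 in no.2 and 15258 shared, as dim probes sit at a background surrogate that scaling moves by the brightness of the array. Without that filter, growth factors and receptors in no.1 had a median of -1.21 with camera's direction turned up (adjusted p = 0.967). The stricter filter left 5 lists in no.1 against control, with fewer genes tested, and the fit to only the groups of the contrast left 6.

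With normexp background correction 7 lists passed in no.1 against no.2, 7 in no.1 against control and 4 in no.2 against control, all of them up, and 9 of the 11, 8 of the 10 and 5 of the 7 list calls were lost in the 3 contrasts, those of every list on the lower side among them. Without the filter on dim probes 8, 8 and 5 were lost, all on the lower side, while 8, 8 and 5 lists passed, all up, against 3, 2 and 2 up with the filter. The medians over all genes were then -0.28, -0.84 and -0.56. Camera thus set each list against dim probes that scaling had moved down, and these losses and gains say little about the lists. With normexp Plod2 was -0.95 in no.1, -0.83 in no.2 and -0.12 between them. With it 4 lists changed camera's direction, of which the unfolded protein response passed in the new one (adjusted p = 0.0219). Their medians were -0.088 for fibroblast identity, -0.075 for lysyl hydroxylases and 0.15 for the unfolded protein response in no.1 against no.2, and -0.098 for hypoxia in no.1 against control. In no.1 against control the log2 fold changes that turned were Col10a1 -0.37 (adjusted p = 0.0134), Itga8 -0.094, Lor -0.10, Ptk2 -0.039 and Raver2 -0.045, and in no.2 Col27a1 -0.015 and Ptk2 -0.066. The offset of 50 lies above the control 75th percentiles of 34.2 and 33.7, so it pulls dim signals together before scaling. Its share in these changes of sign and call was not tested.

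With spike-in scaling, 19342 genes and 16 lists passed in no.1 against control, 15442 genes and 13 lists in no.2, and 15062 genes were shared, as this scaling adds 1 amount per array to all genes. Plod2 in no.1 was -0.21 (adjusted p = 0.567). Genes called lower in no.1 that stood above 0 were Plod1 0.57, Plod3 0.33, P3h4 0.28, Col11a2 0.33, Espn 0.45, Zyx 0.77, Pxn 0.81, Rac3 0.22, Car9 0.38, Chac1 0.43, Ppp1r15a 0.51, Npc2 0.15, Hexa 0.16, Sesn2 0.74, Esr1 0.63, Coro1a 0.028, Cd3e 0.40, Myh11 0.67, Higd1b 0.73, Notch3 0.85, Tnnc1 0.032, Dgat2 0.082, Fabp4 0.61, Dct 0.10 and Pmel 0.82. In no.2 they were Plod3 0.037, P3h4 0.030, Col11a2 0.11, Cdc42ep5 0.22, Zyx 0.24, Sesn2 0.36, Asns 0.57, Ctsz 0.14, Hexa 0.30, Phlda3 0.30, Aen 0.31, Tiparp 0.31, Cd3e 0.18, Higd1b 0.25, Mymk 0.46, Fabp4 0.23 and Foxd3 0.10. Slide and scan were not run as batches, since all arrays shared 1 of each.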

Other observations

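The tests in this part were chosen after the results were seen. Among 156 gene families defined by their symbols, several held more called genes than the rest of the symbols (one-sided Fisher's exact test, Benjamini-Hochberg adjusted over 624 tests). That test takes genes as independent, which members of 1 family need not be, so its p-values may be too small. Over all symbols, 24.1% were called higher and 27.1% lower in no.1, and 12.6% and 16.1% in no.2. The calls are those of the main fit, and averaging the control arrays left 1246 of any kind in no.2, against 6517. In no.1, 9 of 10 genes with the prefix Mcm, which include Mcm3ap and so are not 1 function, were called higher (median 1.99, adjusted p = 0.00223), as were 14 of 19 Nup genes (median 1.23, adjusted p = 0.00133), 22 of 38 Cep genes (median 0.94, adjusted p = 0.00133), 20 of 33 Rbm genes (median 0.83, adjusted p = 0.00133) and 8 of 10 Srsf splicing factor genes (median 1.45, adjusted p = 0.0164). In no.2, 13 of 30 Kif genes, the kinesins, were called higher (median 0.49, adjusted p = 0.00260), with 7 of 10 Mcm genes (median 1.58) and 7 of 12 Pcdhb genes, the beta protocadherins (median 1.25, adjusted p = 0.0127). The medians of these families stayed above 0 under each scaling.

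On the lower side, 46 of 89 odorant receptor (Olfr) genes were called lower in no.1 (median -0.83, above 0 with spike-in scaling) and 31 of 89 in no.2 (median -0.75, 0.52 with spike-in scaling). Their mean level was -2.33 and 46.1% of them were above background on all arrays. In no.2, 10 of 20 keratin (Krt) genes were called lower (median -0.86, 0.41 with spike-in scaling).

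Genes at least 16-fold lower in both groups of treated cells numbered 114, with medians of -5.80 in no.1 and -4.99 in no.2. Spike-in scaling moved the median of all genes from -0.12 to 1.81 in no.1 and from -0.10 to 1.17 in no.2. These shifts are smaller than the 16-fold by which the genes were chosen. Scaling by as much as the spike-ins measure is thereby argued against as the whole cause. With it 100% of these genes were still called lower in both contrasts, with medians of -3.87 and -3.72. The choice of genes came close to fixing that 100%, so it adds no support of its own. Cells of another type present only in the control cultures were looked for with 8 marker lists, whose lowest median was -1.16. None of these lists thus fell 16-fold as a whole. A list median need not fall that far if other cells express some of its markers or if some are dim. In control, 4 of 7 endothelial genes were above background on both arrays. That explanation is therefore not decided. Culture history, tamoxifen itself and loss of LH2 cannot be told apart, since 0 groups had tamoxifen with the gene intact.

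The control arrays differed less than the other pairs. Differences in signal over background are argued against, since among the 7586 brightest probes the robust SD of the difference was 0.076 for control against 0.315 and 0.385, a ratio of 0.241. The file names give 0 h to both control arrays but 24 h and 48 h within each of the other pairs. A difference in time may therefore add to the spread of those pairs, and this was not tested. Whether both control arrays carry 1 RNA stays open, as 26.7% of probes with several spots differed by more than 2 standard errors, which separate labelling of 1 RNA could also give.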
